A study of Mus musculus with 8 samples.

How the data were processed

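Cultured cortical astrocytes from newborn C57BL/6j mice, wild type (WT) or lacking connexin43 (Cx43 KO), were profiled on 2-colour DNA arrays. Per the labels, channel 2 of each array held astrocyte RNA and channel 1 a common reference pooled from adult mouse tissues. The labels give 4 arrays for each genotype, numbered 1 to 4, and a lot batch equal to that number, so that each lot batch held 1 array of each genotype. The group of each array was taken from its title. The title of the array used as Cx43 KO 3 reads only Cx43, without the word KO, and leaving this array out was among the alternatives. The labels do not say whether the samples came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

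The deposited values were signed log ratios of the 2 channels, read here as log2 ratios; the base of the logarithm, the dyes, the scanner, the background correction and the normalization within an array are not given in the sources used here. If the base was another one, every log2 difference would be rescaled by 1 factor, folds would be raised to a power and counts at a fixed fold would change, while signs and p-values would stay as they are. Exact 0 filled 42.4% to 63.4% of the 9568 features on an array and was read as no ratio. Before any centring, the medians of the remaining ratios lay between 0.09 and 0.32, so the arrays had not been set to a common median of these features. The arrays give no counts or intensities here, and their number limits the precision.

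Feature names came from the platform annotation. A single gene symbol was given for 7307 features, covering 5822 symbols, while 318 features named several genes and 1943 were unnamed. Of the features with a single symbol, 7256 had their Entrez number in the gene table of assembly GRCm38.p6, and 0 symbols needed an update. No gene was named from a feature with several symbols. Features of a gene that had a ratio were averaged within each array, and 898 tested genes had more than 1 feature. Where a feature lacked a ratio on some arrays, the arrays could differ in the features averaged. Across 215 genes with 2 features measured on all arrays, the mean log ratios of the 2 features correlated at r = 0.66 across genes, against 0.0084 for random pairs, and the Cx43 KO minus WT differences at r = 0.31, with the same sign in 127 genes. Genes are not independent replicates in these correlations.

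Each array was centred on the median of its ratios, and genes with at least 3 values in each genotype were tested, 3505 in all (2900 named genes and 605 unnamed features, 2596 of them with 8 values). The test was limma 3.58.1 (lmFit and eBayes, R 4.3.3, statmod 1.5.0), two-sided, without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences are Cx43 KO minus WT on the log2 scale, with their standard error (SE) or 95% interval from the same fit. Gene lists with at least 5 tested genes, 26 in number, were tested with limma's camera on the moderated statistics of that fit, with a preset correlation of 0.01 between genes, and adjusted over the lists. The form of camera that takes the fit's statistics was used because genes with missing ratios cannot enter the form that takes values; camera with an estimated correlation and limma's fry ran on genes with 8 values, for 24 lists. Tests of list means per array were exact permutation tests. Genes adjusted over a list alone were not corrected across the lists, so some can pass by chance.

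The lists (31 compared between genotypes, and 1 of adult tissue genes for the reference pool), the tests, the alternatives and the rule for named genes were fixed before the data were examined. That rule took the 12 genes in each direction with the largest difference among those that passed with the same sign in all lot batches. Where fewer than 5 passed, it took the 8 genes in each direction with the smallest p, which did not pass. It added connexins and pannexins, the 3 members of each list with the smallest p, and at most 2 unnamed features in each direction. Genes outside the rule are said to be chosen after their values were seen.

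The direction of the ratio was set by 7 astrocyte markers against 12 genes of adult tissues, with a two-sided exact permutation test over all 50388 arrangements in place of the planned random resamples. Same-numbered WT and Cx43 KO arrays are paired by the lot batch in the labels. Their deviations from the genotype means correlated across genes at r = -0.18, 0.19, -0.13 and -0.19 for numbers 1 to 4, so the ratios themselves showed no shared deviation.

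The scripts were tested on simulated data over 20 draws with 200 changed genes each. The noise was normal, with the spread of each of the 3505 genes and features as moderated by limma. No simulated array was made to stand apart. The shares called hold for that number of changed genes and do not give the power of the real fit. The fit called 12.4% of genes changed 1.5-fold, 64.9% of those changed 2-fold and 99.1% of those changed 4-fold, and 102 of 65680 unchanged ones. A shift of -0.5 in the 21 cell cycle genes was called in 20 of 20 draws, with 0 of 500 tests of unshifted lists called. The simulated genes varied independently, unlike genes on the real arrays, where 23 other splits of the 8 arrays into 4 and 4 called more lists than the real one, up to 9, so the simulation understates false list calls. In the real fit the median SE was 0.22 and the median 95% interval reached 0.50 to each side, 1.41-fold.

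Alternatives were the lot batch as a replicate block, no centring, quantile and scale normalization, genes with 8 values only, features kept apart, a trend and robust prior, array weights, leaving out genes low in astrocytes against the pool, a 1.5-fold minimum, and leaving out each array or lot batch. Centring on features with 8 values, exact 0 kept as a value, leaving out the 3 arrays with the fewest ratios, and camera on genes with 8 values were added after seeing the data. Figures were drawn with matplotlib 3.10.9.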

Results

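RNA from cultured cortical astrocytes of newborn mice was compared between wild-type animals (WT) and animals lacking connexin43 (Cx43 KO), the main gap junction protein of astrocytes. Each of 8 arrays, 4 per genotype, set astrocyte RNA against a common pool of RNA from adult mouse tissues, and each value is the log2 ratio of astrocytes over pool, with base 2 assumed. Between 3506 and 5514 of the 9568 array features carried a ratio on an array (36.6% to 57.6%), and 2818 carried a ratio on all 8 arrays. Gja1, the gene of connexin43, was not analysed here because the probe annotation used names 0 features for it, so the genotype labels could not be checked by the targeted transcript. Of the other connexins and pannexins, Gja4 and Panx1 had a ratio on 0 arrays and Gjc1 on 3 WT and 2 Cx43 KO arrays, so the connexin list had 0 tested genes.

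The genes furthest above the tissue pool included Fabp7 and A2m, and those furthest below it included genes of lung and stomach. Fabp7, a fatty acid binding protein of radial glia and astrocytes, lay at 4.45 ± 0.18 (SD, n = 4) in WT and 3.73 ± 0.57 (SD, n = 4) in Cx43 KO on the log2 scale. A2m, the protease inhibitor alpha-2-macroglobulin, lay at 3.99 ± 0.32 (SD, n = 4) and 4.04 ± 0.29 (SD, n = 4), and the cholesterol exporter Abca1 at 3.81 ± 0.35 (SD, n = 4) and 4.04 ± 0.41 (SD, n = 4). The lung surfactant gene Sftpc lay at -5.95 ± 0.46 (SD, n = 4) in WT and -5.72 ± 0.29 (SD, n = 4) in Cx43 KO. The gastric gene Gkn2 lay at -5.37 ± 0.32 (SD, n = 4) and -5.51 ± 0.47 (SD, n = 4). These genes were among the 12 highest and 12 lowest in the mean of 8 arrays, a choice made after the values were seen. Of 2163 named genes with 8 values, 9 lay at least 4-fold above the pool on all 8 arrays and 25 at least 4-fold below it. The median of 7 astrocyte markers was 1.19 and that of 12 adult tissue genes -1.61, a difference of 2.80 (two-sided exact permutation test over genes, p = 0.039), which set the direction of the ratio, so that the side on which these markers lie is not a separate finding. Single markers, chosen after their values were seen, lay close to 0, with the astrocyte gene Aldoc at 0.11 and, in the tissue list, H2-Eb1 at -0.15 and H2-Aa at 0.07, above the pool. WT and Cx43 KO means correlated at r = 0.94 across these 2163 genes, which are not independent replicates.

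The comparison of Cx43 KO with WT astrocytes asked which transcripts differ when connexin43 is missing. The smallest p among named genes belonged to Cd59a, which encodes an inhibitor of the complement attack complex. Its log2 ratio was 0.81 ± 0.13 (SD, n = 4) in WT and -0.50 ± 0.41 (SD, n = 4) in Cx43 KO, a difference of -1.32 (SE 0.22, limma adjusted p = 0.177). Hmox1, the stress-induced haem oxygenase, differed by 1.43 [0.90, 1.66] (SE 0.38, adjusted p = 0.471), and Tln1, the talin that links integrins to actin, by 0.96 [0.62, 1.12] (SE 0.22, adjusted p = 0.449). Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase, differed by -1.21 (SE 0.26, adjusted p = 0.449), measured on 3 Cx43 KO arrays. None of these passed the test. Here and below, square brackets give the lowest and highest value over leaving out 1 array or 1 lot batch and over quantile and scale normalization. They follow every list mean, and a gene where such a setting changed its difference more than 1.5-fold in size or turned it. Settings that left a gene fewer than 3 values in a genotype gave no value. For a gene not measured on all arrays, the absence of brackets therefore does not show that its difference was stable.

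Among the 8 genes with the smallest p that were higher in Cx43 KO, the differences were 1.56 for the microtubule-binding Camsap1, 0.80 for the amyloid precursor-like Aplp2, 0.87 for the cationic amino acid transporter Slc7a2, 1.19 for Nvl, 0.86 for the chemokine fractalkine (Cx3cl1) and 1.07 for Medag. Among the 8 that were lower, they were -1.18 for 2210409E12Rik, -0.89 for the glucose transporter Slc2a12, -1.34 for the folate receptor Folr2, -1.01 for the nuclear envelope gene Syne1, -1.43 for the mitotic kinase Pbk and -1.20 for Baiap2l1. Camsap1 and Nvl were measured on 3 arrays per genotype and Baiap2l1 on 3 WT arrays. Of the 14 settings behind the brackets, 5 gave a value for Camsap1 and Nvl and 8 for Baiap2l1. All 16 genes had the same sign in each lot batch in which both arrays gave a value. Genes picked for a small p on these same arrays tend to do so, and this is not separate support. The unnamed feature_5444 and feature_7825 differed by 0.69 and 0.70, and the unnamed feature_8746 and feature_1609 by -2.58 (adjusted p = 0.177) and -0.96. With limma, 0 of 3505 genes and unnamed features passed at an adjusted p of 0.05. At an unadjusted p of 0.05, 263 lay below the threshold, 135 higher and 128 lower, where 175 are expected by chance. With the lot batch as a replicate block these counts were 0 and 196. The count at an unadjusted p of 0.05 was 511 with array weights. It was 140 to 384 when leaving out 1 array and 102 to 427 when leaving out 1 lot batch, where the genes tested also changed. Without Cx43 KO 4 the fit called 4, namely Cd59a, Slc13a4 (named after its values were seen) and the unnamed feature_669 and feature_8746, and without WT 2 it called 1, feature_8746.

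**Figure D1:**
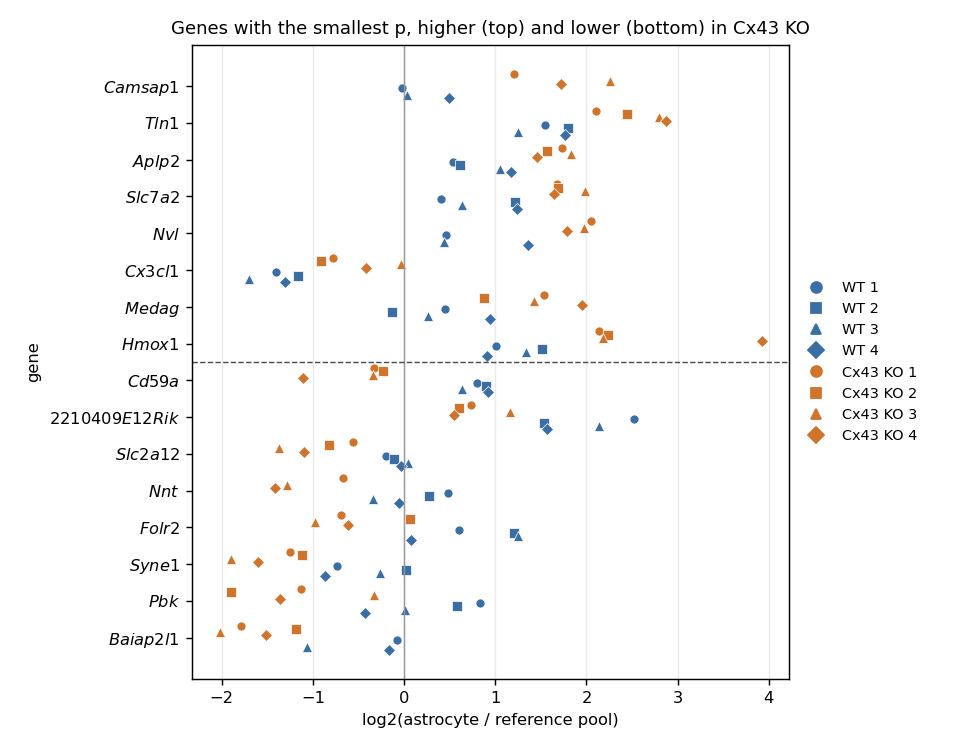
Log2 ratio of astrocytes over the tissue pool (x axis) on each of 8 arrays for the 8 genes higher and the 8 genes lower in Cx43 KO with the smallest p (y axis); blue marks are WT, orange marks Cx43 KO, and the mark's shape gives the replicate number. Cd59a lies between 0.63 and 0.92 in WT and between -1.11 and -0.23 in Cx43 KO, and Hmox1 on Cx43 KO 4 lies at 3.92, above all other arrays.

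Genes of the cell cycle and DNA replication lay lower in Cx43 KO as a group. Of the 42 such genes on the array 21 were tested, of which 18 were lower and 3 higher, with a mean difference of -0.36 [-0.46, -0.11] and a median of -0.41 (limma camera, adjusted p = 2.4e-05). With an estimated correlation between genes, which came to 0.35, the list was not called, adjusted p = 0.82. Foxm1, a transcription factor of the G2/M genes, differed by -0.69 (SE 0.21), the kinase Cdk2 by -0.50 (SE 0.18) and the flap endonuclease Fen1 by -0.59 (SE 0.21). The subunits of the replicative helicase Mcm2, Mcm4, Mcm5, Mcm6 and Mcm7 differed by -0.44, -0.39, -0.77, -0.35 and -0.41, while Cdk6 differed by 0.44, these 6 genes being named after their values were seen. 0 of the 21 passed over all genes tested, and 0 adjusted over the list alone. Across the 15 genes with 8 values, the list mean was 0.52, 0.02, 0.07 and -0.12 on WT 1 to 4 and -0.39, -0.33, -0.04 and -0.0046 on Cx43 KO 1 to 4 (two-sided exact permutation test, p = 0.14). Within lot batches 1 to 4 the difference of these means was -0.91, -0.35, -0.11 and 0.12, and without lot batch 1 the mean over all genes of the list tested there was -0.11 and was not called (adjusted p = 0.346).

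**Figure D2:**
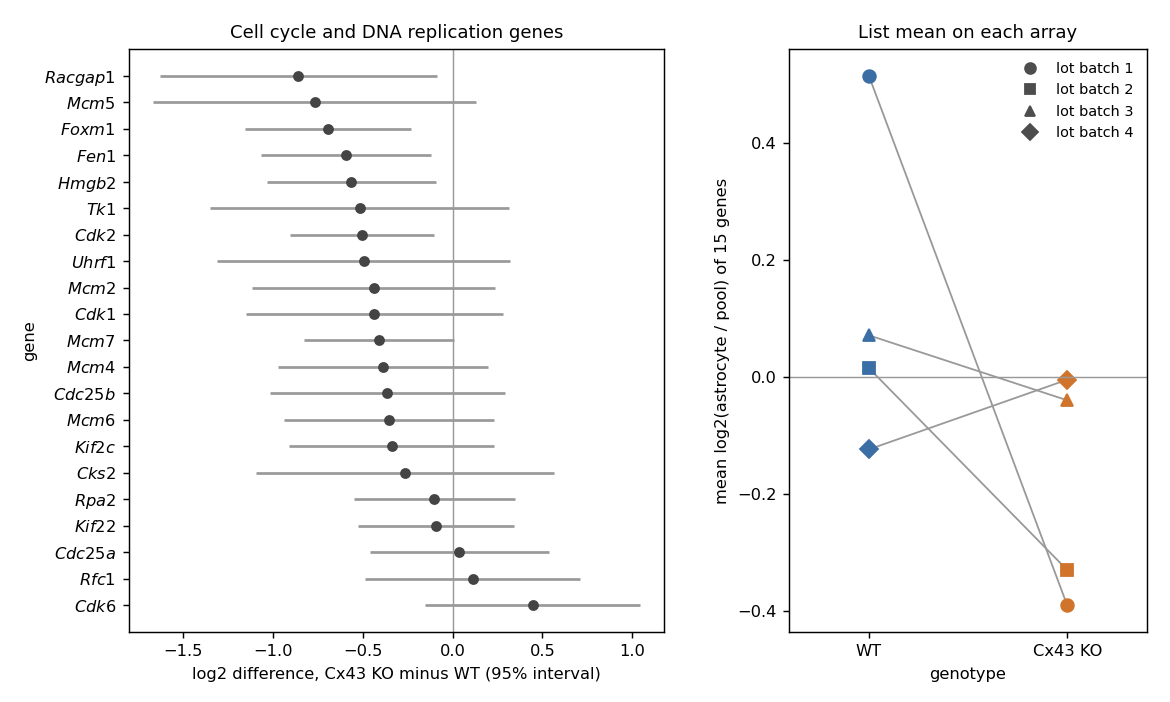
Left, log2 difference of Cx43 KO minus WT with its 95% interval (x axis) for the 21 tested cell cycle and DNA replication genes (y axis), 18 of them below 0; right, mean log2 ratio over the pool of the 15 genes with 8 values (y axis) on each array by genotype (x axis), with lines joining the arrays of a lot batch. The lines go down in lot batches 1, 2 and 3, most in lot batch 1 (-0.91), and up in lot batch 4 (0.12).

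Cyclin-dependent kinase inhibitors and p53 targets lay mostly higher, 8 of 9 tested, with a mean difference of 0.27 [0.21, 0.34] (camera adjusted p = 0.160). Gadd45b, a growth arrest gene, differed by 0.71 (SE 0.21), the p19 inhibitor Cdkn2d by 0.55 [0.35, 0.69] (SE 0.23) and, in the other direction, the p18 inhibitor Cdkn2c by -0.53 [-0.62, -0.35] (SE 0.22). In the 6 of these genes with 8 values, each Cx43 KO array (0.29 to 0.57) lay above each WT array (0.10 to 0.25). That gave an exact permutation p = 0.029, the smallest that 4 against 4 allows, and 0.386 adjusted over 27 lists. Without lot batch 3 this list (mean 0.32) and the apoptosis list (mean 0.27) were called higher, adjusted p = 0.0472 for both. Of 13 apoptosis genes 11 were higher (mean 0.15 [0.08, 0.27], camera adjusted p = 0.491), among them the survival gene Bcl2l1 at 0.53 (SE 0.17) and Bnip3 at 0.65 [0.39, 1.00] (SE 0.30), with Bid at -0.31 [-0.38, -0.19] (SE 0.20). Oxidative stress and glutathione genes went both ways, 7 higher and 6 lower of 13 (mean 0.13 [0.12, 0.14], median 0.04, camera adjusted p = 0.744). The mean rested mostly on Hmox1, which differed by 1.43. Besides Hmox1, Keap1, the repressor of the Nrf2 pathway, differed by 0.67 (SE 0.18) and the thioredoxin reductase Txnrd1 by 0.41 (SE 0.18). Adjusted over the list alone, 2 of these genes passed, Hmox1 and Keap1, both higher, and 0 passed in the kinase inhibitor and apoptosis lists. Limma's fry, which asks whether a list's genes move on balance to 1 side, gave adjusted p = 0.032 for the kinase inhibitors and 0.018 for the oxidative stress list, while camera with an estimated correlation called neither.

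None of the adhesion, matrix and filament lists was called in the reported test. Of 15 integrin and focal adhesion genes 8 were higher (mean 0.06 [-0.04, 0.14], camera adjusted p = 0.817). Tln1 passed when adjusted over the list alone, and the actin-linked genes were Parva at 0.42 [0.13, 0.61] and Flna at 0.38 [0.02, 0.52]. Cadherin, catenin and tight junction genes split 5 to 5 (mean -0.03 [-0.08, 0.39], camera adjusted p = 0.873), with the large cadherin Fat1 at 0.53 [0.06, 0.74], Cdh3 at 0.36 [0.18, 0.47] and the tight junction gene Cgn at -0.56 [-0.56, -0.29]. Without Cx43 KO 4 their mean was 0.34 and was called higher (adjusted p = 0.0448). Of 21 extracellular matrix genes 14 were lower (mean -0.17 [-0.54, 0.08], camera adjusted p = 0.443), with the proteoglycan Vcan at -0.74 and Col6a3 at -1.05 [-1.65, -0.45] but Fmod at 0.59 [0.10, 0.83]. Without Cx43 KO 4 the mean was -0.48 and was called lower (adjusted p = 0.0020). Of 15 actin, tubulin and intermediate filament genes 12 were lower (mean -0.14 [-0.26, -0.04], camera adjusted p = 0.491), among them Tubb2b at -0.50 [-0.87, -0.09] and Marcks at -0.26 [-0.46, -0.08], with Cnn2 at 0.27 [0.04, 0.44]. With scale normalization the mean was -0.26 and was called lower (adjusted p = 0.0225). Adjusted over the list alone, 0 genes passed in the cadherin, matrix and filament lists.

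Growth factors and receptors held single genes with large differences in both directions, 9 higher and 5 lower of 14 (mean 0.01 [-0.08, 0.31], camera adjusted p = 0.834). Igf1 differed by -0.76 (SE 0.20), the platelet-derived growth factor receptor Pdgfra by -2.27 (SE 0.63, 3 arrays per genotype) and Smad7, an inhibitor of transforming growth factor signalling, by 0.86 (SE 0.25). Pdgfra has 3 features, and its arrays may differ in the features averaged. Adjusted over the list alone 4 genes passed, Igf1, Pdgfra, Smad7 and Fgf1 at 1.39, the last named after its values were seen. Over all genes tested, limma's adjusted p was 0.471 for Igf1, 0.578 for Pdgfra and 0.572 for Smad7. Wnt and Notch genes were 4 higher and 5 lower (mean -0.08 [-0.16, 0.13], camera adjusted p = 0.817), with Notch4 at -0.78 (3 arrays per genotype), Jag2 at 0.29 [0.13, 0.39] and Ctnnb1 at 0.28 [-0.08, 0.42]. Calcium and purinergic signalling genes split 6 to 6 (mean -0.0038 [-0.04, 0.05], camera adjusted p = 0.873), with Prkcb at 0.31 [0.13, 0.38], Gnai3 at 0.28 [0.10, 0.42] and the calcium pump Atp2a2 at -0.40 [-0.55, 0.14]. Of 5 glutamate, potassium and water handling genes 3 were higher (mean -0.05 [-0.13, -0.07] in the 4 settings with enough genes, camera adjusted p = 0.873), with the glycine transporter Slc6a9 at -0.40 [-0.42, -0.16], Glud1 at 0.52 [0.32, 0.70] and the water channel Aqp1 at -0.55 [-1.40, 0.09]. Only 4 immediate early and AP-1 genes were tested, too few for the list test, with Klf6 at 0.09 [-0.43, 0.35], Ier5 at 0.01 [-0.20, 0.32] and Btg2 at 0.01 [-0.13, 0.21]. In the last 4 lists 0 genes passed when adjusted over the list alone.

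None of the metabolic and housekeeping lists was called. Glycolysis genes were 5 higher and 2 lower (mean 0.21 [0.04, 0.30], median 0.40, camera adjusted p = 0.443), with Aldoa at 0.43 [0.24, 0.56], Hk1 at 0.44 [0.19, 0.70] and Gys1 at 0.40 [0.23, 0.67]. Oxidative phosphorylation genes were 6 higher and 16 lower (mean -0.03 [-0.15, 0.12], camera adjusted p = 0.688), with Ndufa3 at -0.36 [-0.48, -0.23], Cox6b2 at 0.66 [0.48, 1.01] and Uqcr10 at 0.30 [0.25, 0.55]. Ribosomal protein genes split 6 to 6 (mean 0.07 [-0.08, 0.21], camera adjusted p = 0.817). The members with the smallest p, Rpl7l1 at 0.29 [0.18, 0.43], Rps4l at 0.40 and Rps27l at 0.14 [0.03, 0.24], are ribosomal protein-like genes rather than core subunits. Translation factors were 9 higher and 6 lower (mean 0.08 [0.01, 0.12], camera adjusted p = 0.817), with Eef1a1 at 0.40 [0.24, 0.59], Eif3a at 0.25 [0.04, 0.37] and Eif4a3 at -0.27 [-0.44, -0.09]. Proteasome subunits were 8 higher and 5 lower (mean 0.05 [-0.05, 0.10], camera adjusted p = 0.817), with Psmc5 at -0.34 [-0.52, -0.26], Psmd11 at 0.34 [0.21, 0.47] and Psme1 at 0.39 [0.11, 0.57]. Heat shock proteins and chaperones were 7 higher and 4 lower (mean 0.0060 [-0.07, 0.06], camera adjusted p = 0.873), with mitochondrial Hspa9 at 0.60, Ppia at -0.30 [-0.47, -0.08] and Cct4 at -0.30 [-0.47, -0.20]. Cholesterol and fatty acid synthesis genes were 5 higher and 6 lower (mean -0.04 [-0.17, 0.03], camera adjusted p = 0.860), with Acly at 0.54, Mvd at -0.30 [-0.45, -0.11] and Fabp7 at -0.72 [-1.39, -0.49]. In these 7 lists 0 genes passed when adjusted over the list alone.

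Immune genes and markers of other cell types varied between arrays of the same genotype. Cx43 KO 1 and 2 lay below every WT array in the microglia and fibroblast lists, and Cx43 KO 4 above every other array. The mean of 10 microglia and macrophage markers with 8 values was 2.57 on Cx43 KO 4, against -0.21, 0.09 and 1.02 on Cx43 KO 1 to 3 and 0.54 to 1.18 on the WT arrays. On the same array 5 astrocyte markers had a mean of 0.50, against 1.57 to 2.00 on the other 7 arrays, and 4 reactive astrocyte markers a mean of 2.54, against 0.69 to 1.29. Interferon and antigen presentation genes (0.92 against -0.14 to 0.14) and cytokine, chemokine and NF-kB genes (1.14 against -0.46 to -0.08) also stood apart there. Not all members did so. Of the reactive markers Steap4 (3.57, highest other 1.06) and Cd44 (2.88, highest other 2.23) were highest there, but Stat3 and Tm4sf1 were not. Among interferon genes H2-Eb1 was lowest there (-0.94, lowest other -0.81), and H2-Aa, Ifngr1, Ifi27 and Irf8 were not highest. Nor were Cx3cl1, Socs2 and Stat3 among the cytokine genes. Fibroblast, meningeal and mural markers ran from -0.87 and -0.63 on Cx43 KO 1 and 2 to 2.07 on Cx43 KO 4, with 0.54 to 1.42 in WT, and the mean of 17 extracellular matrix genes went with them, from 0.10 and -0.08 to 1.44.

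**Figure D3:**
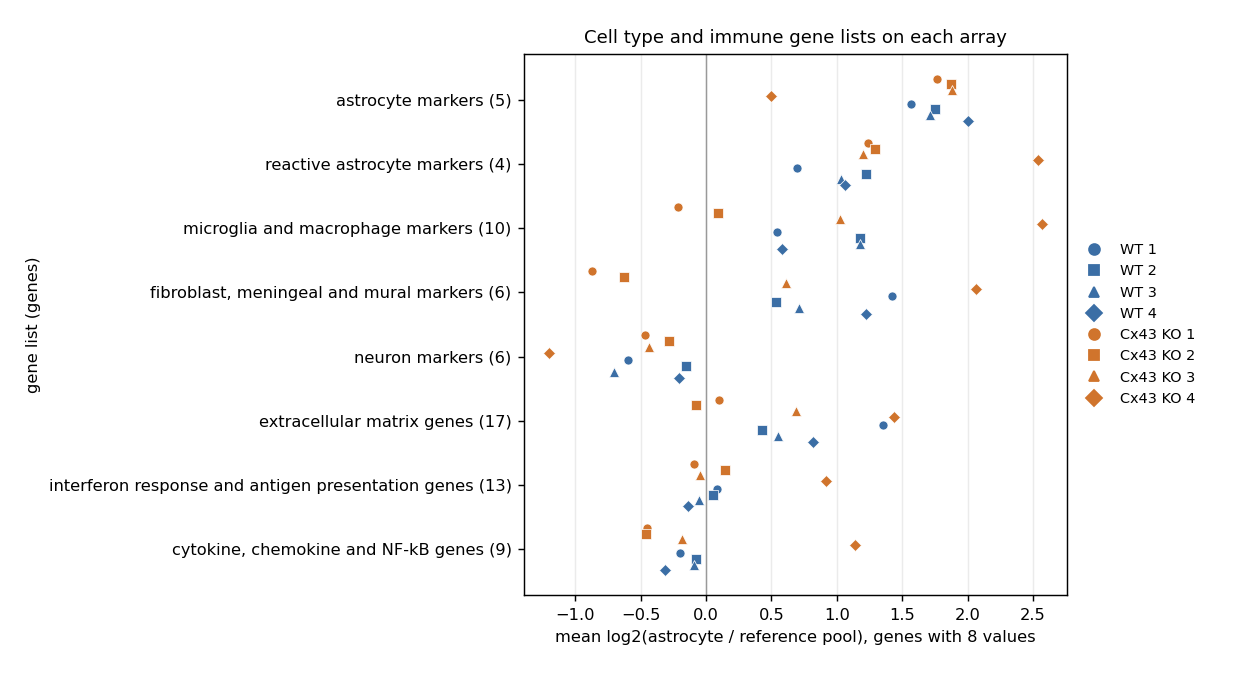
Mean log2 ratio of astrocytes over the tissue pool (x axis) for 8 gene lists (y axis, number of genes with 8 values in brackets) on each array; blue marks are WT, orange marks Cx43 KO, and the mark's shape gives the replicate number. Cx43 KO 4 has the highest mean of microglia and macrophage markers (2.57) and the lowest of astrocyte markers (0.50).

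Between genotypes, none of these lists was called. Microglia and macrophage markers were 5 higher and 7 lower of 12 (mean -0.06 [-0.67, 0.36], camera adjusted p = 0.817), with Lgmn at 0.46 [0.26, 0.68], Rac2 at 1.03 [0.32, 1.36] and Tyrobp at -0.64 [-1.14, -0.32]. Without Cx43 KO 4 the mean was -0.57 and was called lower (adjusted p = 0.0114). Astrocyte markers were 3 higher and 4 lower (mean -0.28 [-0.52, 0.16], camera adjusted p = 0.443), with Fabp7, the tested gene nearest to Gja1 on its chromosome, at -0.72 [-1.39, -0.49], Id4 at -0.71 and Ttyh1 at -0.42 [-0.72, 0.15]. Id4, at -0.52 on Cx43 KO 4 against 3.05 and 1.58 on Cx43 KO 1 and 3, could not be tested without it. Their mean was 0.11 without Cx43 KO 4, while with scale normalization it was -0.52 and was called lower (adjusted p = 0.0225). Reactive astrocyte markers were 5 higher and 2 lower (mean 0.57 [0.18, 0.76], camera adjusted p = 0.491), with Steap4 at 1.67 [0.86, 2.37], Cd44 at 0.53 [0.23, 0.79] and Stat3 at 0.30 [0.03, 0.45], and had a mean of 0.18 without Cx43 KO 4. Interferon and antigen presentation genes were 11 higher and 5 lower (mean 0.21 [-0.05, 0.39], camera adjusted p = 0.443), with Irf9 at 0.49, Adar at 0.59 [0.32, 0.89] and H2-Aa at -0.46 [-0.65, -0.26], and had a mean of -0.05 without Cx43 KO 4. Without Cx43 KO 1 their mean was 0.36 and was called higher (adjusted p = 0.0307). Cytokine, chemokine and NF-kB genes were 5 higher and 4 lower (mean 0.18 [-0.24, 0.37], camera adjusted p = 0.491), with Nfkb2 at 0.86 [0.55, 1.10], and had a mean of -0.19 without Cx43 KO 4. Without the 3 sparsest arrays, a setting chosen after seeing the data, their mean was 0.46 and was called higher (adjusted p = 0.0454). Cx3cl1 passed when adjusted over the list alone.

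Fibroblast, meningeal and mural markers were 4 higher and 3 lower (mean -0.50 [-1.19, -0.14], camera adjusted p = 0.817), with the meningeal enzyme Ptgds at -2.45 [-3.25, -1.61] (SE 0.80) and Col3a1 at -1.64 [-3.07, -0.08] (SE 1.30). Without Cx43 KO 4 their mean was -0.97 (adjusted p = 0.058). Neuron markers split 4 to 4 (mean -0.02 [-0.33, 0.15], camera adjusted p = 0.963), with Vamp2 at 0.81, Mapt at -0.38 [-0.68, -0.0042] and Dpysl3 at -0.52 [-0.91, -0.02], and had a mean of 0.15 without Cx43 KO 4. Of oligodendrocyte lineage genes 3 were tested, Pdgfra, which passed when adjusted over the list alone, Cnp at -0.27 [-0.54, 0.13] and Trf at 0.55 [-0.52, 1.09], and of endothelial genes 2, Cdh5 at -0.62 [-0.95, -0.10] and Mmrn2 at -0.04 [-0.40, 0.53]. The ependymal and choroid plexus list had 0 tested genes. Adjusted over the list alone, 0 genes passed in the astrocyte, reactive astrocyte, microglia, interferon, fibroblast, neuron and endothelial lists. The sign of mean and camera differed for the cadherin, calcium, heat shock and neuron lists, and that of median and mean for the calcium, glutamate, neuron and fibroblast lists, all of them uncalled.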

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

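All tests weighed here on Cx43 KO 4 and the fibroblast covariate were chosen after the results were seen; the splits of the arrays into other groups and the covariate of measured features were set before, and the count of lists over the splits after.

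Some arrays lay far from the other 3 of their genotype, by the gap to the nearest array over the range, in 17 of 232 groups of 4 values tested, where chance gives about 1 in 20 groups, 11.6 here; 8 of the 17 were on Cx43 KO 4. On that array the mean of astrocyte markers was 0.50 (others 1.76 to 1.88) and that of reactive astrocyte markers 2.54 (others 1.20 to 1.29). Hmox1 was 3.92 (others 2.14 to 2.23), Cd59a -1.11 (others -0.34 to -0.23), Glud1 1.19 (others 1.86 to 1.99), Aqp1 0.85 (others -2.56 to -2.50), Cdkn2c -1.12 (others -0.48 to -0.34) and Cnp -1.53 (others -0.06 to 0.13). On Cx43 KO 3 Slc7a2 was 1.98 and Flna 3.10, and on Cx43 KO 2 Trf was 0.013 (others -4.16 to -3.60). On WT 1 the means of the actin, tubulin and intermediate filament list (1.24), the oxidative phosphorylation list (-0.75) and the ribosomal protein list (0.18, others -0.41 to -0.36) stood apart, as did Cnn2 (1.76) and Steap4 (-1.55). On WT 4 the cholesterol and fatty acid synthesis list lay at 0.60 (others 0.94 to 0.96).

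Cx43 KO 4 held high microglia and macrophage genes, with Adgre1 at 4.91 (highest other array 2.63), Ccl3 at 3.03 (0.41), Rac2 at 3.04 (0.66) and Cybb at 3.43 (2.04), genes chosen for their values. Only 1 of the 4 Cx43 KO arrays lay above the highest WT array in the list mean, and 8 of 10 of the list's genes were highest on Cx43 KO 4, against 20.5% of 2163 named genes (exact hypergeometric p = 8.9e-05). List and array were picked for the pattern and the genes vary together, so these values restate it and argue neither for genotype nor against noise over the array. More microglia or macrophages in that sample may explain it, but the shift was wider: all 5 astrocyte markers were lowest there, where 22.8% of named genes were, 5 of 6 fibroblast markers were highest, and Lgmn (0.68) and Tyrobp (1.06) were not. Other cells, an activated state of the same cells, noise and an effect of the genotype that shows in some cultures stay open.

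Of the 35 splits of the 8 arrays into 4 and 4, the real one included, 6 gave the cell cycle list a camera p as small as the real 9.2e-07, the smallest of the other splits being 4.6e-12, so chance cannot be excluded for this list. Of the 8 splits that part the arrays of all 4 lot batches, 2 gave a p as small, and of the other 27, which keep some lot batches together, 4 did. The number of measured features as a covariate left the mean difference at -0.40 (110% of the uncorrected -0.36), camera adjusted p = 1.1e-05, and the fibroblast list mean as a covariate left it at -0.25 (70.7%), camera adjusted p = 0.014, so the list stayed called with either. But the 95% interval of the per-array list mean included 0 with the measured features (-0.76 to 0.08), with the fibroblast mean (-0.60 to 0.19) and with no covariate (-0.73 to 0.10). The bound set in advance for the measured features used camera's p alone, which takes a preset correlation of 0.01 where 0.35 was estimated, and so it was too weak. Since the interval included 0 with no covariate too, it decides for neither covariate. With the measured features the difference did not shrink, and their number overlapped between genotypes (3506 to 5514 in WT, 3798 to 5353 in Cx43 KO). That gave this explanation no support, though the wide interval does not exclude it. The fibroblast mean cannot be told apart from the genotype with 8 arrays. The cell cycle and fibroblast list means correlated over the 8 arrays at Pearson r = 0.69 (exact permutation p = 0.053) and Spearman rho = 0.62 (exact permutation p = 0.11), the only relation computed; without Cx43 KO 1 and 4, r was 0.75 (exact permutation p = 0.11).

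For single genes, 6 of the 35 splits gave at least the 263 genes of the real split at an unadjusted p of 0.05, the highest other split giving 567, so chance cannot be excluded. That highest split put Cx43 KO 4 with WT 1 to 3 and WT 4 with Cx43 KO 1 to 3, and 2 of the 8 splits that part all lot batches, the real one and this one, gave at least 263. Of the 35 splits, 31 called at least the 1 list of the real split, the highest other calling 9, and 23 called more than the real one, so chance cannot be excluded for the count of lists. Splits that call several times the real count may reflect a structure among the arrays other than genotype. They may also reflect camera's preset correlation of 0.01, where estimates ran from -0.09 (kinase inhibitors) to 0.69 (astrocyte markers). These were not told apart. Correlated across genes, WT 4 was closest to Cx43 KO 3 (r = 0.91) and Cx43 KO 1 (r = 0.88). Its r was 0.85 to 0.91 with Cx43 KO 1 to 3 and 0.85 to 0.88 with WT 1 to 3. Cx43 KO 4 was closest to Cx43 KO 3 (r = 0.79) and WT 1 (r = 0.78) and furthest from Cx43 KO 1 and 2 (r = 0.67 with both). Its r was 0.72 to 0.78 with WT 1 to 3. Both arrays of lot batch 4 thus lay at least as close to most arrays of the other genotype as to their own. The ranges overlap, so these correlations do not decide whether the 2 arrays were swapped. A swap of the lot batch 4 arrays was not tested further, since Gja1 was not analysed here.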

How the results depend on the processing

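The settings that centre on features with 8 values, keep exact 0 as a value, leave out the 3 sparsest arrays, or run camera on genes with 8 values were chosen after seeing the data. The count of genes passing limma's test was 0 in the reported fit, 2 with array weights (Cd59a and feature_8746), and 0 to 4 when leaving out 1 array; it was 0 in 22 settings, among them leaving out each lot batch. The count of lists called, 1 in the reported test, was 2 with quantile normalization, 4 with scale normalization, 3 with array weights, 1 to 4 when leaving out 1 array, 0 without lot batch 1, 4 without lot batch 3, 3 without lot batch 4, 0 with an estimated correlation, 2 with fry and 2 without the 3 sparsest arrays. The extracellular matrix list, lower, was called with quantile and scale normalization, array weights, and without Cx43 KO 4, lot batch 3 or lot batch 4, while its mean was 0.08 without lot batch 1. Called besides were the actin and astrocyte lists, lower, with scale normalization, the microglia list, lower, with array weights and without Cx43 KO 4 or lot batch 4, the kinase inhibitor and apoptosis lists, higher, without lot batch 3, the interferon list, higher, without Cx43 KO 1, and the cytokine list, higher, without the 3 sparsest arrays. The spread of an array's ratios, as median absolute deviation, was 0.51 to 0.60 on WT arrays and 0.59 to 0.66 on Cx43 KO arrays. Scale normalization sets these spreads equal, which tends to lower Cx43 KO against WT in genes above the pool. The matrix, actin and astrocyte lists, called lower there, had median WT levels of 0.64, 0.54 and 1.26, so that step itself pushes them lower. The cause of the other changes was not tested.

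The cell cycle list mean was -0.11 (adjusted p = 0.346) without lot batch 1 and -0.31 in the genes with 8 values, where an estimated correlation gave adjusted p = 0.82 and fry 0.783. Leaving out 1 array gave -0.46 to -0.21, with adjusted p from 3.2e-06 to 0.031, and called the list each time; without WT 1 it was -0.21 and without Cx43 KO 1 -0.25. In its other settings the list stayed lower and called. The cadherin list mean ran from -0.080 to 0.34 when leaving out 1 array, took either sign under other settings too, and was called only without Cx43 KO 4. With the lot batch as a replicate block, 0 genes and the same 1 list were called (cell cycle mean -0.38, adjusted p = 5.4e-05); it changed no call. Of the values of list means under other settings, 517 kept sign and call, 87 changed sign without a call, 17 were called only there and 3 lost their call. The remaining 1, the cadherin list without Cx43 KO 4, was called with a mean of the other sign. Camera's own direction for it, higher, was the same as in the reported test. Of 2027 values of 99 named genes and features, 1987 kept their direction and 5, all of Cd59a and feature_8746, passed. Gja1 gave no value under any setting. The direction of the ratio held in all 10 settings. The share of features with a ratio, 36.6% on the sparsest array, limits which genes could be tested.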

Other observations

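The tests of Nnt and of the oxidative stress list were chosen after the results were seen; that of the neighbours of Gja1 was set before. Single genes, chosen after their values were seen and tested as no group, set Cx43 KO 4 apart from the other 7 arrays. Smoc2, a matricellular gene, lay at 2.77 there against a mean of -1.39 on the others, Col3a1 at 3.67 against -0.29, Bgn at 2.68 against 0.09, and Tspo, a mitochondrial protein of activated glia, at 1.86 against -0.81. The galectin Lgals9 lay at 1.09 against -1.91 and the chemokine Ccl9 at 2.28 against -0.58. The neuronal and glial cytoskeletal gene Map2 lay at -2.54 against 0.62, Ttyh1 at -0.59 against 1.29 and Gnao1 at -1.76 against 0.10. The antiviral genes Oasl2 (2.84 against 0.36) and Ifitm3 (2.62 against 0.60) were also high.

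A strain difference between the genotypes was considered as a hypothesis, since a targeted gene can carry flanking sequence from the strain of the stem cells. The 30 tested genes nearest to Gja1 on its chromosome, ordered by the gene table of assembly GRCm38.p6, had a mean absolute moderated statistic at the percentile of 61.0 of 10000 random sets, so as a set they did not differ more than other genes. Of these 30 genes 3 lay below an unadjusted p of 0.05, against 7.50% of all genes and features tested: Fabp7, the nearest, at -0.72, and Mtres1 (-0.67) and Mrln (-0.86), the last pair named after their values were seen. The 30 genes were taken by rank, with no limit on distance, among 148 tested genes of that chromosome. A test of this set does not exclude an effect on such single genes or on a shorter segment. Nnt, which is known to carry a deletion in C57BL/6J, differed by -1.21 (limma adjusted p = 0.449), and the lowest WT array (-0.34) lay above the highest of 3 Cx43 KO arrays (-0.67). A background that differs at Nnt may explain this only if the genotypes differ in strain, with the deletion on the Cx43 KO side. Both genotypes are given here as C57BL/6j, and Nnt is not among the 30 genes near Gja1. Nnt was picked for its small p and did not pass, so background and chance cannot be told apart here.

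The mean of the 13 oxidative stress and glutathione genes lay between -0.13 and -0.11 on the WT arrays and between -0.02 and 0.03 on the Cx43 KO arrays, higher in 4 of 4 lot batches. Of the 35 splits 1, the real one, gave a difference as large as the real 0.13, the highest other giving 0.08. Because this list was singled out among 27, the exact permutation p = 0.029 came to 0.386 after adjustment. Hmox1 (1.43) and Keap1 (0.67) carried the list's mean difference, while the median difference over the 13 genes was 0.04. Hmox1 was 3.92 on Cx43 KO 4 against 2.14 to 2.23 on Cx43 KO 1 to 3, yet the list mean there was 0.02. The other members together therefore lay lower on that array, and the close agreement of the Cx43 KO means rests in part on this offset.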
